A study of Mus musculus with 4 samples.

How the data were processed

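Macrophages sorted from mouse brain cortex were profiled by droplet single-cell RNA sequencing, in which each droplet's bead adds a cell barcode to the transcripts of the cell it captures. Per the labels, 2 genotypes were compared: mice carrying a conditional (floxed) allele of Maf, and mice carrying that allele together with a Cre recombinase driven by Crybb1. Each genotype is 1 pool of 2 mice, and each pool gave a gene expression library and an antibody-tag library, which makes the 4 samples. The 2 mice of a pool had been stained with different hashtag antibodies, B0301 and B0302, before they were sorted into 1 tube. The sort took live cells by CD45.2 and CD11b and excluded cells stained for Ly6C, Ly6G, CD43, CD44 or NK1.1. The 4 samples were treated here as 1 batch. Per the labels' protocols, a high-throughput 3' kit was overloaded with a target of 40000 cells per sample.

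Per the submitters' processing notes, Cell Ranger and Seurat were used with the genome build GRCm39. Their versions, settings and cell-calling thresholds are not given in the sources used here. The deposited lists are text: 1 cell barcode per line for each genotype, named as the filtered output, 1 feature per line with its identifier, name and type, and a reference of the hashtag sequences. None of these columns is a measured value, and expression values and hashtag counts per cell were not analysed here. The tests of expression and cell type shares fixed for the case of count matrices were therefore not run, cells were not assigned to mice, and doublets were not assessed. No filter on cells was applied.

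The barcode lists carry the short names WT and KO. They were matched to the genotypes through the library names in the labels, which use the same short names. No value used here, such as the level of Maf, checks that match.

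Barcodes were counted after removing the constant suffix. Counts of barcodes carry exact Poisson intervals at 95%, the ratio of the 2 counts carries an interval from the exact (Clopper-Pearson) binomial, and shares of barcodes carry exact binomial intervals. Because cells were not assigned to mice and each genotype is 1 library, these intervals cover counting error only. They do not cover the spread between mice or between libraries, and no test between genotypes was made. The number of barcodes that the beads could carry was computed from the lists as the number of joinable pairs of the 8-base leading and trailing segments seen in the Maf-flox list. Segments were joinable when the bases at positions 8 and 9 formed a dinucleotide seen in that list. The number of barcodes expected in both lists by chance is the product of the list sizes over that number. Barcode pairs 1 or 2 bases apart were counted within each list and between the lists. The counting steps were tested on simulated lists: 50 of 50 planted neighbours at 1 base were recovered, and 20 simulated pairs of lists shared 479 to 560 barcodes where 509 were expected.

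Features were compared row by row. Gene identifiers were matched to a table of gene names with their version numbers removed: 31961 of 33696 were found and 29374 carried the same symbol. No gene coordinates are given, because the annotation at hand is of another genome build. The genes named in the text were fixed before the data were examined: Maf, Crybb1, the genes of the sort, 7 lists of gene groups and 13 lists of cell type markers, reported as present or absent among the features; some of these genes are not reported by name here. The analysis used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The alternatives left out barcodes found in both lists or 1 base from another barcode, allowed 1 mismatch or 2, and ignored the case of symbols.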

Results

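The study asked how loss of c-MAF, the transcription factor encoded by Maf, alters brain macrophages, in particular those along blood vessels. Brain macrophages were sorted from Maf-flox mice and from Maf-flox mice with Crybb1-Cre. Crybb1 encodes a beta-crystallin and is also expressed in cells of the microglial lineage. Each genotype was 1 library holding the pooled cells of 2 mice, and cells were not assigned to mice here, so values below have no replicates. The files used here list the cells and genes of each library. The levels of Maf and of every other gene were not analysed here, and the effect of genotype on expression and on cell type shares is not reported. The depth per cell is unknown for the same reason.

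The Maf-flox library held 44990 cell barcodes (95% exact Poisson interval 44575 to 45408). The Maf-flox Crybb1-Cre library held 41679 (41280 to 42081). The labels give a target of 40000 cells per sample, so the barcodes came to 112% and 104% of it. The Maf-flox Crybb1-Cre library held 3311 fewer barcodes than the Maf-flox library, a ratio of 0.926 (0.914 to 0.939). The deficit was not uniform over barcode sequences: in a split chosen after the data were seen, the ratio was 1.01 (0.986 to 1.03) among barcodes with at most 3 G bases, which were 40.5% of the Maf-flox and 44.0% of the Maf-flox Crybb1-Cre barcodes, and it lay above 1 at 1 G (1.09) and 2 G (1.05). These intervals cover counting error only. The number of barcodes in a library also follows the number of cells loaded and the calling of cells. With 1 library per genotype, these cannot be separated from genotype, and hashtag counts would not change that. No test of whether the difference exceeds that between mice was made, and hashtag counts per cell were not analysed here. The barcodes include any droplets with more than 1 cell.

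Both libraries were read against the same 33698 features, with 0 rows that differed, so each gene that could be counted in one genotype could be counted in the other. They comprised 33696 genes and the 2 hashtags. The targeted gene Maf had 1 feature (ENSMUSG00000055435). Crybb1, whose regulatory sequence drives the recombinase, had 1 feature (ENSMUSG00000029343). No feature was named for the Cre transgene itself, so its transcript has no row of its own under that name. The sample labels spell the driver Cribb1, a symbol carried by 0 features, whereas the series design text spells it Crybb1.

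The genes of the sort were all among the features. Ptprc (ENSMUSG00000026395) encodes CD45 and Itgam (ENSMUSG00000030786) encodes CD11b, the 2 antigens used to select cells. The genes of the excluded antigens were Ly6c1 and Ly6c2 for Ly6C, Ly6g for Ly6G, Spn for CD43, Cd44 for CD44 and Klrb1c for NK1.1, each with 1 feature. Antibody features covered the 2 hashtags and no antigen of the sort.

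All 127 distinct genes of the fixed lists had exactly 1 feature each. The perivascular macrophage list had 10 of 10 genes, among them Mrc1 and Cd163, which encode scavenging receptors, Lyve1, a hyaluronan receptor, and Pf4, a chemokine. The microglia list also had 10 of 10, among them P2ry12, a purine receptor, Tmem119, and Sall1, a transcription factor. The 2 lists shared 0 genes. The MHC class II list had 5 of 5 genes, including H2-Aa, Cd74 and the regulator Ciita. The interferon response list (Ifit1, Isg15 and Irf7 among others), the list of genes induced by dissociation (Fos, Jun, Egr1 and Hspa1a among others) and the lysosome and lipid list (Apoe, Lpl, Trem2 and Gpnmb among others) each had 10 of 10. The vascular signalling list had 12 of 12, including the growth factors Vegfa, Pdgfb and Igf1 and the cytokines Il1b and Tnf. No symbol of these lists was among the 26 symbols carried by 2 identifiers.

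Markers of the other cell types that a brain sort can hold all had a feature as well. The monocyte list had 6 of 6 (Ly6c2 and Ccr2 among them), the neutrophil list 5 of 5 (S100a8 and S100a9), the dendritic cell list 6 of 6 (Flt3 and Xcr1), the T or natural killer cell list 6 of 6 (Cd3e and Nkg7) and the B cell list 4 of 4 (Cd79a and Ms4a1). Endothelial markers had 5 of 5 (Cldn5 and Pecam1), mural cell markers 4 of 4 (Pdgfrb and Rgs5), astrocyte markers 4 of 4 (Aqp4 and Gfap), oligodendrocyte markers 4 of 4 (Mbp among them) and neuronal markers 3 of 3 (Snap25 and Syt1). Markers of dividing cells had 4 of 4 (Mki67 and Top2a). The 8 microglia-like and 9 perivascular macrophage-like markers were also present. Presence among the features states that reads could be assigned to a gene, not that the gene was expressed. The features are what reads were counted against, so these counts of list genes describe no cell of either library.

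The hashtags that told apart the 2 mice of a pool were read in the second read after 10 bases. Hashtag B0301 had the 15-base sequence ACCCACCAGTAAGAC and B0302 had GGTCGAGAGCATTCA. They differed at 11 of 15 positions. The same pair of hashtags was used in both genotypes, so a hashtag identifies a mouse only together with its library.

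The cell barcodes had 16 bases. In both libraries positions 8 and 9, counted from the 5′ end, held 4 of the 16 possible dinucleotides, and the Maf-flox list held 3836 different leading segments and 3840 different trailing segments of 8 bases. These segments can form 3682560 barcodes. The libraries had 505 barcodes in common (95% exact Poisson interval 462 to 551), where a random draw from that set would give 509 (465 to 554). A barcode in both libraries therefore has to be kept apart by its library when cells are merged. No barcode of one library was 1 base from a barcode of the other. Within libraries, 6 pairs of barcodes 1 base apart were found in the Maf-flox Crybb1-Cre library (interval 2.2 to 13.06) and 0 in the Maf-flox library (upper limit 3.69). The intervals overlap, which does not test whether the libraries differ. All 6 pairs held a trailing segment absent from the Maf-flox list. Segments of the Maf-flox list could hardly form such pairs. Of their 303 pairs of trailing segments 1 base apart, 1 differed after the first base, which position 8 sets. The absence of such pairs in the Maf-flox library and between the libraries therefore says little.

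The base composition of the barcodes differed between the libraries. G made up 24.6% of barcode bases in the Maf-flox library and 23.8% in the Maf-flox Crybb1-Cre library, and C made up 25.2% and 25.8%. G was lower in the Maf-flox Crybb1-Cre library at 16 of 16 positions, by 0.24 to 1.26 percentage points, and the 95% binomial intervals of the libraries did not overlap at 9 of them. Barcodes had 3.93 ± 1.59 G bases in the Maf-flox library and 3.80 ± 1.60 in the Maf-flox Crybb1-Cre library (mean ± SD over barcodes). The ratio of barcodes, Maf-flox Crybb1-Cre over Maf-flox, which was 1.01 among barcodes with at most 3 G, was 0.845 (0.826 to 0.864) among those with at least 5 G. By single counts of G, the ratio was 1.09 (1.03 to 1.16) at 1 G, 1.05 (1.01 to 1.09) at 2 G, 0.957 (0.930 to 0.984) at 3 G and 0.912 (0.887 to 0.937) at 4 G.

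**Figure D1:**
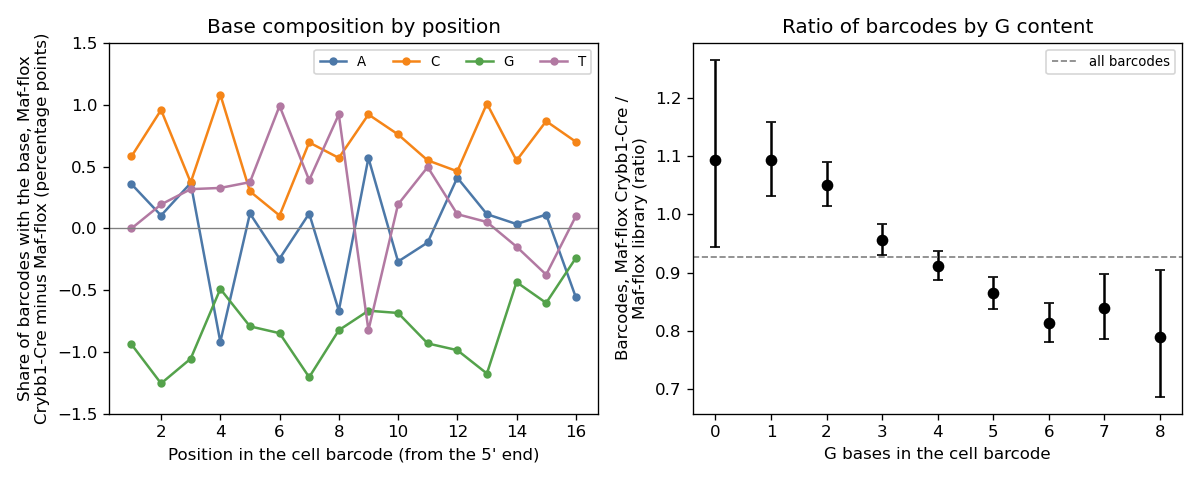
Left, the share of barcodes with each base, Maf-flox Crybb1-Cre minus Maf-flox library in percentage points, by position in the barcode; right, the number of barcodes in the Maf-flox Crybb1-Cre library over that in the Maf-flox library by the number of G bases, for 0 to 8 G, with 95% exact intervals for counting error and the ratio of all barcodes, 0.926, as a dashed line. G lies below 0 at 16 of 16 positions and C above 0 at 16 of 16. The ratio runs from 1.09 at 0 and 1 G to 0.789 at 8 G, with 0.814 at 6 G and 0.840 at 7 G. At 0 G the interval, 0.944 to 1.27, includes 1. Among the few barcodes not drawn, the ratio was 1.17 (0.798 to 1.72) at 9 G and 0.875 (0.270 to 2.76) at 10 G.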

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

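Of 19 alternative values for 10 results, 14 stayed within their bound (1.5 times a count, or the counting interval of a ratio or share) and 5 moved. Several of the 14 could not have moved, so their number does not measure robustness. Removing a constant suffix changes no count. With 0 pairs 1 base apart in the Maf-flox list and 0 between the lists, leaving out such barcodes or allowing 1 mismatch had nothing to change there. Leaving out shared barcodes or barcodes 1 base from another kept the ratio of the libraries at 0.926, and the number of shared barcodes stayed at 505 with 1 mismatch allowed. Leaving out barcodes 1 base from another left 41667 in the Maf-flox Crybb1-Cre library. Ignoring the case of symbols left 127 list genes with a feature. The ratio of barcodes, Maf-flox Crybb1-Cre over Maf-flox, moved to 1.01 among barcodes with at most 3 G and to 0.845 among those with at least 5 G, a split chosen after the data were seen, and the cause was not tested. Counting pairs exactly 2 bases apart in place of 1 gave 9085 within the Maf-flox library, 8090 within the Maf-flox Crybb1-Cre library and 16877 between them, by construction far more. The 4 alternatives that need expression values (another normalization, no filter on low counts, a block for the hashtag number, and leaving out each mouse) were not run. No paired analysis was possible because the labels do not pair mice across genotypes. The mice of each genotype were also pooled in 1 library, and hashtag counts, which would assign cells to mice, were not analysed here. The depth of the libraries is unknown here, and without hashtag counts each comparison is limited to counting error. For the number of barcodes, hashtag counts would not separate genotype from library.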

Other observations

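The tests of explanations in this part, on shared barcodes, G content and barcodes 1 base apart, were chosen after the results were seen.

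The 505 barcodes in both libraries were weighed as a trace of reads assigned to the wrong library. That would raise their number above the upper end for a random draw, 554, and it did not. The interval of the observed number allows an excess of at most 41.8 barcodes, or 0.1% of the Maf-flox Crybb1-Cre list. That limit takes the expected 509 as exact, for even draws of both lists from 1 barcode set. The difference in G content described below departs from such draws. Transcripts of one library read at low level in barcodes of the other are not excluded by this, since they need not add a barcode to a list. No biological explanation was tested.

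The lower G content of barcodes in the Maf-flox Crybb1-Cre library is unexpected because a bead's barcode is fixed before it meets a cell. For counting error in draws from 1 barcode set, a limit of 1 of the 16 positions with separate intervals was set after the data were seen. It was not computed from such draws. Separate intervals were seen at 9 positions. The 16 positions are not independent, because the allowed dinucleotides tie positions 8 and 9. Different bead lots, or a loss of G-rich barcodes in sequencing or in the calling of cells, cannot be told apart from each other or from genotype, because there is 1 library of each and depth per barcode was not analysed. Any such hypothesis has to account for the fall of the ratio, Maf-flox Crybb1-Cre over Maf-flox, with G content. The ratio was 1.09 at 1 G, 1.05 at 2 G, 0.957 at 3 G, 0.912 at 4 G and 0.845 at 5 or more G. The numbers of cells loaded are not given in the sources used here. A ratio above 1 is therefore not in itself an excess of barcodes.

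The 6 pairs of barcodes 1 base apart in the Maf-flox Crybb1-Cre library all held a trailing segment that the Maf-flox library lacked, and the 2 barcodes of each pair differed by C12T in 4 pairs, C10T in 1 and C11T in 1 (positions from 1 at the 5′ end of the barcode, the base of the trailing segment known from the Maf-flox library first). There were 4 such segments in 8 barcodes, 5 of them with GTGTTCAT, whereas a trailing segment had 10.8 barcodes on average in that library. Over the whole Maf-flox Crybb1-Cre list, independent draws from its segments would give 1.10 pairs 1 base apart, with an upper end of 4, and 6 were seen. Such draws give every segment the same chance, including the 4 that the Maf-flox list lacked, and treat pairs as independent. Those 4 segments held 1 to 5 barcodes each, below the average of 10.8. The 1.10 is therefore too high for pairs that hold them. The 6 pairs were also not independent, since 5 of the 6 pairs share 1 segment. The 0 pairs between the libraries, scaled to a list of this size, give an upper limit of 1.71. That limit is no background for the 6, because segments of the Maf-flox list could hardly form such pairs. Of their 303 pairs of trailing segments 1 base apart, 1 differed after the first base, which position 8 sets. Read errors, or a bead carrying 2 forms of its barcode, stay open as candidate explanations for these 6 barcodes, 5 of which share a segment, because a test would need the transcripts and hashtags of each pair. If so, these droplets would be counted more than once among the 41679, a share too small to alter the ratio of the libraries, which was 0.926 without them.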
